A study of Homo sapiens with 4 samples.

How the data were processed

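The series holds 4 RNA-seq libraries of HepG2 cells, 2 from the solvent control DMSO and 2 from cells given 20 µM isoginkgetin for 24 h. Groups and replicate numbers were taken from the sample titles, and dose and time from the series' design text. Per the labels' protocols, total RNA was extracted with a spin-column kit, polyadenylated RNA was isolated on magnetic beads and libraries were made with a non-directional second-strand kit, so reads carry no strand. The submitters' processing notes name STAR 2.7.0, featureCounts and the builds hg19 and mm10, without saying which build served these libraries. The gene annotation, the setting for reads shared between genes and the total counts per library are not given in the sources used here.

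The authors deposited one table of their own comparison between the groups, with 1 row per gene. Per the file headers, the authors' table has the columns of a DESeq2 results table without the test statistic; the version, the model formula and the group in the numerator are not given in the sources used here. The authors' deposited mean normalized count is read as a signal averaged over the libraries after division by size factors, and is not a count of any one library. The authors' deposited log2 fold change and its standard error are on the log2 scale. The authors' deposited p-value and adjusted p-value are per gene, and the adjusted values follow the Benjamini-Hochberg procedure over 20024 genes, a number recovered from the adjusted p times the rank over the p. Every row has an adjusted p under 0.05, so a gene outside the table has no value here, and whether it was tested or how it moved is not known.

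Positive log2 fold changes are called higher and negative ones lower, and are read as isoginkgetin over DMSO, the usual order. The headers do not name the order, and it was not inferred from the values of any gene. The absolute fold change over its SE was smaller than the normal deviate of the gene's own p-value, with a median ratio of 0.585 at mean normalized counts under 30 and 0.990 at 1000 or more. The fold changes therefore look like shrunken estimates, a step no header or label records, and those of genes with low counts are likely to understate the change and cannot be read as plain ratios of means.

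Precision follows the level of the gene. The median SE was 1.11 at mean normalized counts under 30 and 0.0805 at 1000 or more, on the log2 scale. No fold change closer to 0 than 0.117 reached the table. The depth per library is unknown, and no counting interval is given. For the 85 genes with a mean normalized count over 20000, the SE implies a median coefficient of variation between replicates of 3.16%, if the SE is read as that of an unshrunken difference.

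The tests planned before the data were examined needed a value per library and could not be run: neither a count model, nor gene set tests with a correlation between genes, nor a fit with the replicate number as a block, nor leaving out libraries. The authors' per-gene results were used in their place. Each of 31 gene lists, holding 572 entries and fixed before the data were examined, was matched to the table by current or older symbol. For the 30 lists with a gene in the table, the split of higher and lower members was compared with that of all other genes in the table by Fisher's exact test (two-sided, scipy 1.17.1), and p-values were adjusted over the 30 lists by the Benjamini-Hochberg procedure, with a threshold of 0.05. This test asks only whether the members that changed leaned one way more than the other changed genes. It takes genes as independent. The count adjusted over the list alone was not computed, because p-values of members outside the table are not held. As an alternative test, the number of higher members was set against 10000 random lists of the same size drawn within 20 bins of mean normalized count. The median log2 fold change of each list was set against the central 95% of the medians of these random lists. On simulated data over the 8727 genes, the Fisher test gave p under 0.05 for 2.65% of unchanged lists, 69.4% of lists with 80% of members in one direction and 100% of lists with all members in one direction. Only lists with at least 10 genes in the table were simulated, and these p-values were not adjusted. The shares therefore do not cover smaller lists, such as fatty acid synthesis (6 genes), TGF-beta and YAP targets (8) and metallothioneins (9). With random members, 6% of lists lay outside the central 95% of the random lists.

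Named genes followed a rule fixed before the data were examined. They are the 7 genes with the highest and the 7 with the lowest log2 fold change at a mean of at least 10 CPM (counts scaled to a common library total), up to 2 members of each list with the largest absolute change at that level (up to 4 for the autophagy machinery, autophagy receptors and lysosome), and MAP1LC3B, SQSTM1, ATF4, CDK6 and ALB. A mean normalized count of 183.4, computed with the summed mean normalized counts of the table in place of a library total, stood in for 10 CPM, and 6550 genes reached it. The condition that both treated libraries lie on one side of both controls could not be applied. Some genes and results are not reported here. Genes named in the closing section outside this rule were chosen after their values were seen.

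Gene types, exon numbers and transcript lengths came from GENCODE 29, matched by symbol, with older symbols resolved through RefSeq synonyms. This annotation is on another build than the authors', so no coordinates are given. Of the 8727 genes, 8056 (92.3%) had a type and 7524 were protein-coding. Values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. Alternatives chosen after seeing the data were stricter adjusted p thresholds (0.01, 0.001 and Bonferroni), fold changes of at least 1.5 and 2, a mean normalized count of at least 183.4, protein-coding genes only, fold changes centred on the median of the table, equal summed mean counts in both groups, and the random lists. Families of genes sharing the letters of their symbols were tested where at least 10 were in the table, 87 in all, along with 10 further groups, which were also set against such random lists.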

Results

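Polyadenylated RNA was sequenced from HepG2 cells, a human liver cancer line labelled here as hepatoblastoma, in 2 libraries of the solvent control DMSO and 2 libraries of cells given 20 µM isoginkgetin for 24 h. Isoginkgetin is a plant biflavonoid known as an inhibitor of pre-mRNA splicing. The comparison between the groups asks which transcripts differ after the treatment, and the series title points to autophagy. All values come from the authors' deposited table, which gives a mean normalized count over the libraries, a log2 fold change with its standard error (SE) and p-values, for genes with an adjusted p under 0.05. Values per library are not analysed here, so no total count per library and no spread between single libraries can be given. The table does not name the group in the numerator. Higher and lower below mean a positive and a negative log2 fold change, read as isoginkgetin over DMSO, the usual order of treatment and control. If the order was the other way round, every direction below would be turned. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

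The authors' deposited table holds 8727 genes, of which 4493 (51.5%) were higher and 4234 were lower. Its p-values and adjusted p-values together imply that 20024 genes were tested, so that 43.6% of them passed the threshold. Most changes were small, and 68.6% of the genes changed by less than 2-fold. At 2-fold or more the balance turned, with 1253 genes higher and 1488 lower. Below 2-fold 3240 were higher and 2746 lower, and these splits differed (Fisher's exact test, two-sided, p = 2.97e-13). The median log2 fold change was 0.63 among higher genes and −0.78 among lower genes.

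**Figure D1:**
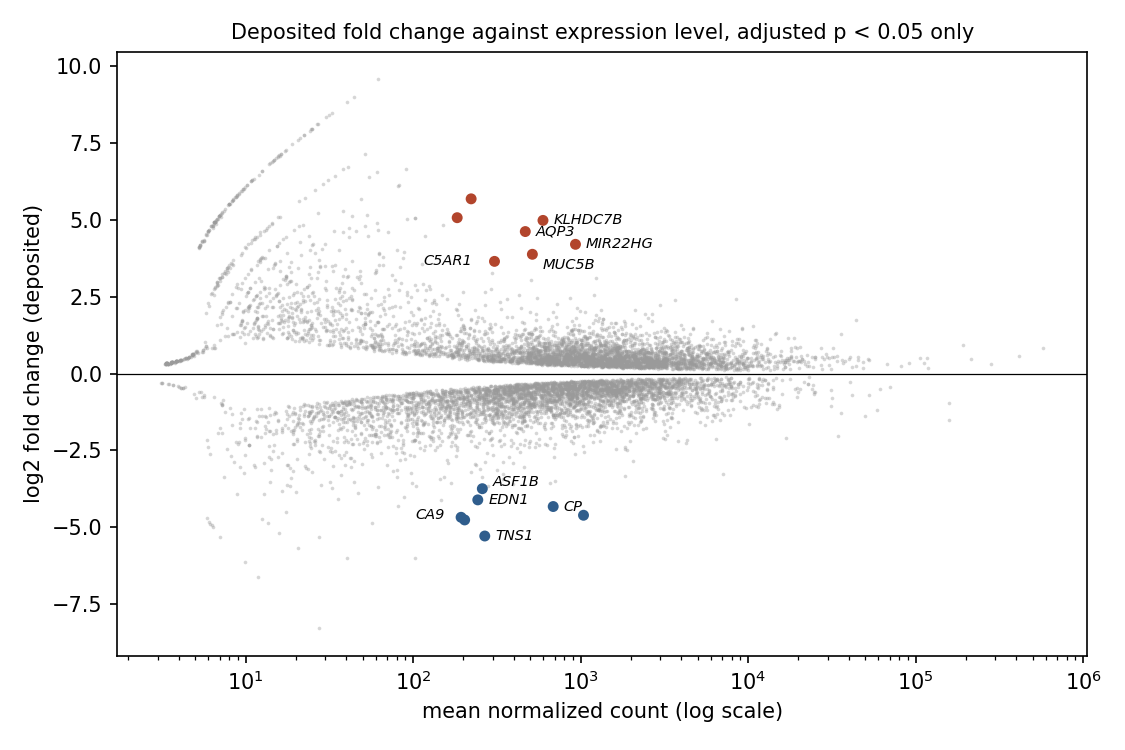
Log2 fold change of the 8727 genes in the authors' deposited table (vertical axis) against their mean normalized count (horizontal axis, log scale), each point a gene with an adjusted p under 0.05. Coloured points are the 7 genes with the highest and the 7 with the lowest log2 fold change at a mean normalized count of at least 183.4, with names except for clone-named genes, and no gene lies closer to 0 than 0.117.

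The largest increases at a mean normalized count of at least 183.4, which stood for 10 CPM (counts scaled to a common library total), belonged to genes of varied function. In the authors' deposited table KLHDC7B had a log2 fold change of 4.98 (SE 0.22), AQP3, a water and glycerol channel, of 4.62 (SE 0.23) and MIR22HG, the host transcript of a microRNA, of 4.21 (SE 0.15). MUC5B, a secreted mucin, stood at 3.88 and C5AR1, a complement receptor, at 3.65 in the authors' deposited table. Above these the authors' deposited table lists the clone-named genes RP11-479G22.8 at 5.69 and RP11-325K4.3 at 5.07. Among the lowest genes of the authors' deposited table were TNS1, a focal adhesion protein, at −5.29 (SE 0.33), CA9, a hypoxia-induced carbonic anhydrase, at −4.68 (SE 0.36) and CP, the copper carrier ceruloplasmin, at −4.33 (SE 0.17). EDN1, the precursor of endothelin, was at −4.11 and ASF1B, a histone chaperone of dividing cells, at −3.75 in the authors' deposited table. The clone-named RP11-284F21.7 (−4.76) and RP11-284F21.10 (−4.61) complete the lowest 7 of the authors' deposited table. The libraries carry no strand, so reads of overlapping genes, clone-named transcripts included, cannot be assigned to one of them.

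Genes of the autophagy machinery were mostly higher. Of 32 listed genes of the autophagy machinery, 21 are in the authors' deposited table, and 18 of these were higher and 3 lower, with a median log2 fold change of 0.46. This share was above that of all other genes in the table (Fisher's exact test, two-sided, adjusted p = 0.00691 over 30 lists). Against random lists of like expression the number of higher members also passed (adjusted p = 0.0114). The median, however, lay within the central 95% of the medians of those lists (−0.50 to 0.49), so the lean is one of direction rather than of size. MAP1LC3B, which encodes the LC3B protein of the autophagosome membrane, had a log2 fold change of 1.37 (SE 0.07, adjusted p 4.21e-73) in the authors' deposited table. Its relative GABARAPL1 was at 1.19 (SE 0.15), the ULK1 complex subunit ATG101 at 0.99 (SE 0.13) and ATG16L1, part of the LC3 conjugation enzyme, at 0.81 (SE 0.10) in the authors' deposited table. At 2-fold or more 4 of the 5 members left were higher, too few for the test to pass.

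Autophagy receptors went both ways, with 5 higher and 4 lower among the 9 of 13 in the table (adjusted p = 1, Fisher's exact test). SQSTM1, the cargo receptor p62, had a log2 fold change of 1.004 (SE 0.05, adjusted p 2.92e-76) in the authors' deposited table, and TAX1BP1 was at 0.73 (SE 0.07). The mitophagy receptors BNIP3L and BNIP3, both induced by hypoxia, were lower at −1.40 (SE 0.11) and −0.66 (SE 0.06) in the authors' deposited table. Lysosomal genes showed no shift as a list: 13 were higher and 7 lower among the 20 of 27 in the table (adjusted p = 0.364, Fisher's exact test). Within that list the authors' deposited table gives log2 fold changes of 0.80 for ATP6V1B2 and 0.71 for ATP6V0D1, subunits of the proton pump, 0.66 for the membrane protein CD63 and −0.74 for the cholesterol transporter NPC1.

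**Figure D2:**
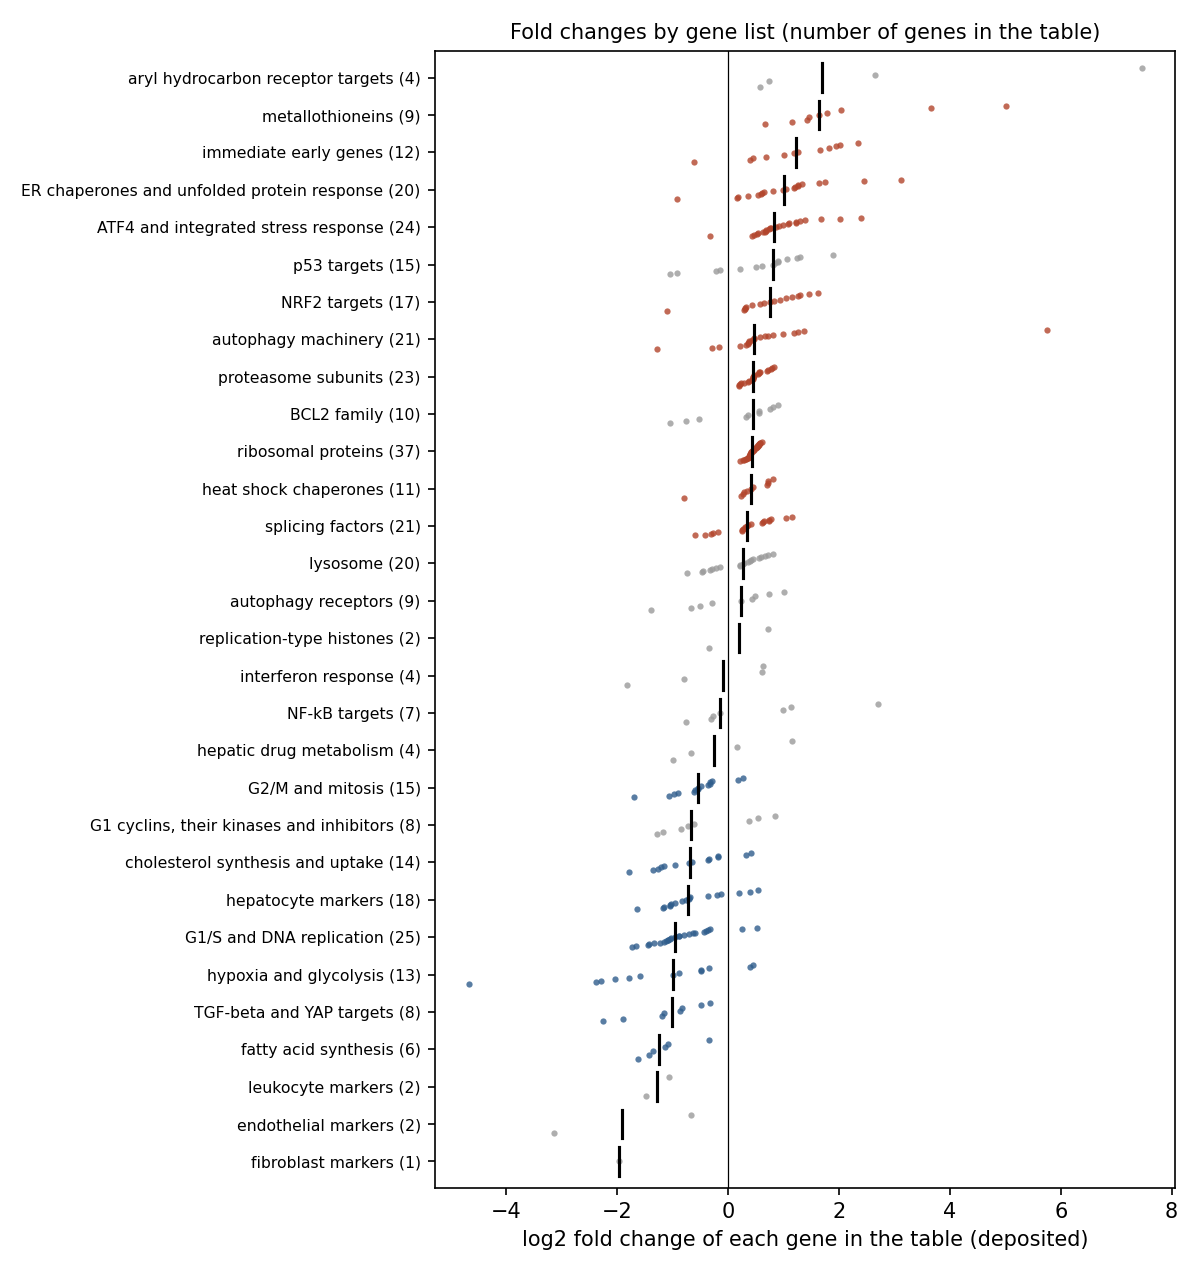
Log2 fold change (horizontal axis) of each listed gene in the authors' deposited table, by gene list (vertical axis, number of genes in the table in brackets), each point a gene and each black bar the median of its list. Red lists held more higher genes and blue lists more lower genes than the rest of the table (Fisher's exact test, adjusted p under 0.05), and grey lists passed in neither direction; the metallothionein list stands high with 9 of 9 genes above 0, and fatty acid synthesis low with 6 of 6 below 0.

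Genes of cellular stress responses were higher as groups. Of the 24 of 32 ATF4 and integrated stress response genes in the table, 23 were higher (median 0.82, adjusted p = 3.51e-05, Fisher's exact test). ATF4 itself, the transcription factor of that response, was at 0.73 (SE 0.05), PPP1R15A, which reverses eIF2α phosphorylation, at 2.40 (SE 0.08) and ATF3 at 2.02 (SE 0.13) in the authors' deposited table. Of the 20 of 22 ER chaperone and unfolded protein response genes in the table, 19 were higher (median 1.01, adjusted p = 0.000269, Fisher's exact test). DNAJB9, an ER co-chaperone, had a log2 fold change of 3.11 (SE 0.11) and HERPUD1, a factor of ER-associated degradation, of 2.44 (SE 0.05) in the authors' deposited table. All 23 proteasome subunits in the table, of 31 listed, were higher (median 0.45, adjusted p = 4.28e-06, Fisher's exact test), with PSMC4 at 0.83 and PSMD12 at 0.79 in the authors' deposited table. NRF2 targets were higher in 16 of 17 cases, of 20 listed (median 0.75, adjusted p = 0.00148, Fisher's exact test). GCLM and GCLC, the subunits of the first enzyme of glutathione synthesis, stood at 1.61 (SE 0.08) and 1.46 (SE 0.07) in the authors' deposited table. At 2-fold or more the NRF2 call was lost, with 6 of 7 higher (adjusted p = 0.164).

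All 9 genes of the metallothionein list, which includes the zinc exporter SLC30A1, were higher (median 1.64, adjusted p = 0.0109, Fisher's exact test). MT1F was at 2.03 (SE 0.13) and MT1X at 1.78 (SE 0.25) in the authors' deposited table, and reads of these near-identical genes may be divided unevenly among them. MT1G at 1.64 (SE 0.53), MT1E at 1.15 (SE 0.33) and MT2A at 1.46 (SE 0.22) in the authors' deposited table were named after their values were seen. At mean normalized counts of 1634, 2093 and 6818, their SEs lay far above the median of 0.0805 at 1000 or more. Their values are thus less certain than others at that level. Of the 12 of 17 immediate early genes in the table, 11 were higher (median 1.22, adjusted p = 0.0152, Fisher's exact test), among them ATF3, which is also on the ATF4 list, and the phosphatase DUSP5 at 1.81 (SE 0.08) in the authors' deposited table. At a mean normalized count of at least 183.4 the call was lost, with 8 of 9 higher (adjusted p = 0.0648). Heat shock chaperones were higher in 10 of 11 cases, of 16 listed (median 0.41, adjusted p = 0.0241, Fisher's exact test), a call that was lost against random lists of like expression (adjusted p = 0.0877), at an adjusted p under 0.001 (0.0643), with Bonferroni (0.106) and at 1.5-fold (0.317). HSPH1 was at 0.80 and the small chaperone HSPB1, the exception, at −0.80 in the authors' deposited table. Ribosomal protein genes were higher in all 37 cases, of 38 listed (median 0.42, adjusted p = 6.65e-10, Fisher's exact test). RPL18 had a log2 fold change of 0.61 (SE 0.05) and RPL7 of 0.58 (SE 0.05) in the authors' deposited table, and processed pseudogenes can share reads with such genes. Of other protein-coding genes matched on transcript length and mean normalized count, 77.3% were higher too, with a gene counted each time it was matched. By symbol alone, 49 of 51 RPL and 36 of 41 RPS genes were higher, and the 7 lower ones were pseudogenes, S6 kinase genes and the paralog RPS27L. The higher ones hold pseudogenes too, since 7 of the 10 ribosomal protein pseudogenes in the table were higher.

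Splicing factors, the machinery that isoginkgetin is known to act on, were higher in 16 and lower in 5 of the 21 of 34 genes in the table (median 0.34, adjusted p = 0.0490, Fisher's exact test). That call was lost against random lists of like expression (adjusted p = 0.253) and at a mean normalized count of at least 183.4 (0.0507). RBM39 was at 1.14 (SE 0.06) in the authors' deposited table. U2AF1, a subunit of the factor that binds the 3′ splice site, was at 1.05 (SE 0.21) there, and a near-identical gene copy in some genome builds makes its value uncertain in the authors' deposited table.

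Genes of cell division were lower. Of the 25 of 28 G1/S and DNA replication genes in the table, 23 were lower (median −0.95, adjusted p = 4.86e-05, Fisher's exact test). GINS1, a subunit of the replicative helicase, was at −1.74 (SE 0.10) and the transcription factor E2F1 at −1.67 (SE 0.10) in the authors' deposited table. Of the 15 of 26 G2/M and mitosis genes in the table, 13 were lower (median −0.54, adjusted p = 0.0107, Fisher's exact test), with HMMR at −1.70 and the kinetochore motor CENPE at −1.06 in the authors' deposited table. G1 cyclins, their kinases and inhibitors split into 3 higher and 5 lower among 8 of 16 (adjusted p = 0.595, Fisher's exact test). The median of this list, −0.67, lay below the central range of the medians of random lists of like expression (−0.59 to 0.56). That range was not adjusted over the lists. CDK6, a G1 kinase, was at −1.17 (SE 0.07, adjusted p 1.06e-64) and RBL1, a relative of the retinoblastoma protein, at −1.28 (SE 0.13) in the authors' deposited table. Replication-type histones were represented by 2 of 12 genes, 1 in each direction (adjusted p = 1, Fisher's exact test), and H1F0, a linker histone also made outside replication, was at −0.34 in the authors' deposited table.

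Hepatocyte genes were lower in 15 and higher in 3 of 18 cases, of 21 listed (median −0.73, adjusted p = 0.0107, Fisher's exact test). FGA, a fibrinogen chain, was at −1.64 (SE 0.05) and the plasma protein AHSG at −1.17 (SE 0.05) in the authors' deposited table. ALB, the albumin gene, was to be reported whatever its result, but it was looked for among the genes past the threshold and gave no value, so it is not analysed here and its direction is unknown. Lipid genes moved the same way. Cholesterol synthesis and uptake genes were lower in 12 of 14 cases, of 24 listed (median −0.69, adjusted p = 0.0150, Fisher's exact test), with the lanosterol synthase LSS at −1.35 (SE 0.10) in the authors' deposited table. This call was lost among genes with an adjusted p under 0.001, with 9 of 11 lower (adjusted p of the list 0.0946). Fatty acid synthesis genes were lower in all 6 cases, of 13 listed (median −1.25, adjusted p = 0.0244, Fisher's exact test), and with fold changes centred on the median of the table all 6 stayed lower at an adjusted p of 0.0551. The desaturases FADS2 and FADS1 were at −1.62 (SE 0.10) and −1.44 (SE 0.07) in the authors' deposited table.

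Hypoxia and glycolysis genes were lower in 11 of 13 cases, of 17 listed (median −0.99, adjusted p = 0.0231, Fisher's exact test). CA9 again stood lowest, and the glycolytic regulator PFKFB4 was at −2.39 (SE 0.17) in the authors' deposited table. The hypoxia call was lost with Bonferroni, with 10 of 12 lower (adjusted p = 0.0746). TGF-beta and YAP targets were lower in all 8 cases, of 10 listed (median −1.01, adjusted p = 0.0107, Fisher's exact test), with the matricellular protein CTGF at −2.25 (SE 0.06) and ANKRD1 at −1.90 (SE 0.10) in the authors' deposited table.

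**Figure D3:**
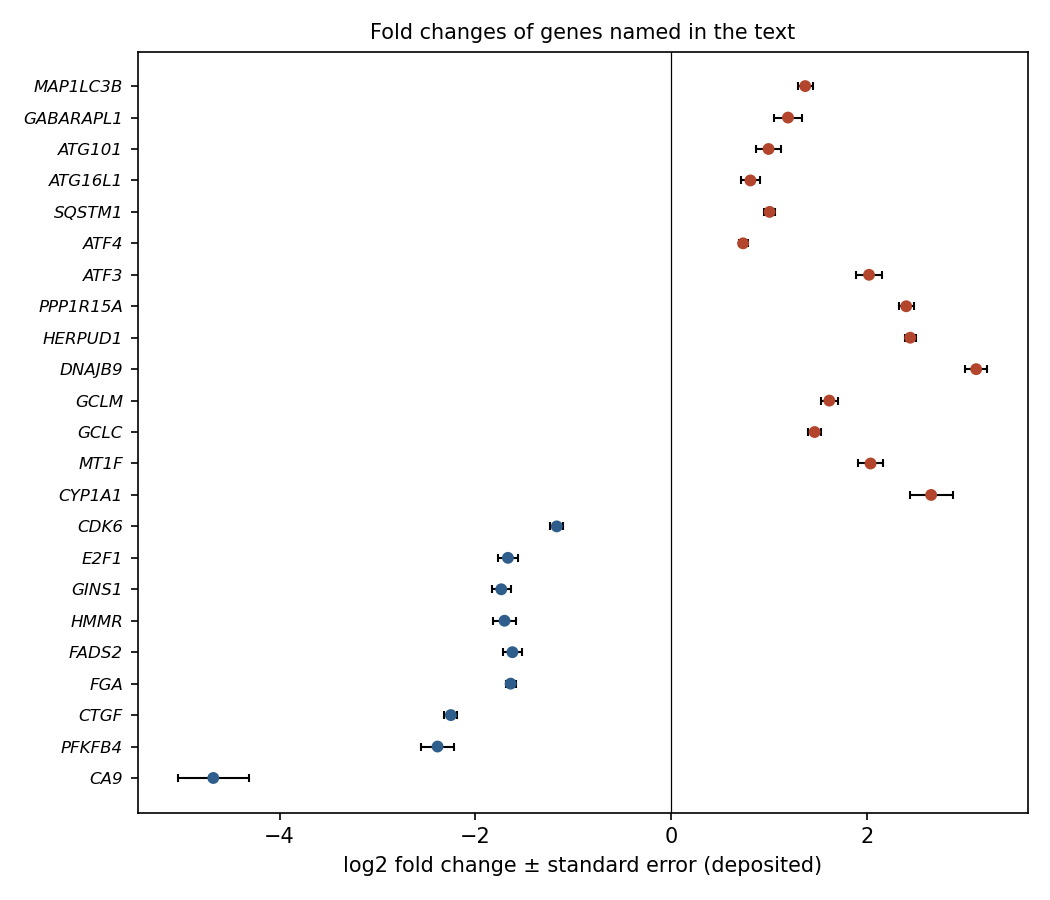
Log2 fold change with its SE (horizontal axis, bars 1 SE to each side) of 23 genes named in the text (vertical axis), as given in the authors' deposited table. Red points lie above 0 and blue points below it, from 3.11 for DNAJB9 down to −4.68 for CA9.

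The remaining lists passed in neither direction by Fisher's exact test. Among p53 targets 11 were higher and 4 lower of 23 listed (adjusted p = 0.198, Fisher's exact test). Their median of 0.81 lay above the central range of the medians of random lists of like expression (−0.54 to 0.51). Such ranges were not adjusted over the lists. The authors' deposited table gives 1.89 for C12orf5, which encodes TIGAR, 1.29 for the stress cytokine GDF15 and −1.04 for the apoptosis effector BAX. BCL2 family genes split into 7 higher and 3 lower of 15 listed (adjusted p = 0.451, Fisher's exact test), with BAX again lower and the BH3-only gene PMAIP1 at 0.89 in the authors' deposited table. Aryl hydrocarbon receptor targets were higher in all 4 cases of 8 listed (adjusted p = 0.198, Fisher's exact test). Their median of 1.69 also lay above its range (−1.27 to 1.07). The medians of the BCL2 family, drug metabolism, NF-kB and interferon lists lay within theirs. CYP1A1, the classic target of that receptor, was at 2.65 (SE 0.22) and TIPARP at 0.73 (SE 0.16) in the authors' deposited table. Hepatic drug metabolism genes split evenly, 2 and 2 of 13 listed (adjusted p = 1, Fisher's exact test), with UGT2B7 at −0.99 and ABCB1 at −0.67 in the authors' deposited table. NF-kB targets stood at 3 higher and 4 lower of 16 listed (adjusted p = 0.830, Fisher's exact test), with CXCL8 at 1.13 and SOD2 at −0.76 in the authors' deposited table. Interferon response genes were 2 higher and 2 lower of 11 listed (adjusted p = 1, Fisher's exact test), with IFI6 at −0.80 and ISG15 at 0.63 in the authors' deposited table.

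Few markers of other cell types were among the changed genes, and a marker outside the table may still be expressed. Lists with only 1 or 2 genes in the table could not have passed even with every member in one direction. The table holds 1 of 8 fibroblast markers (adjusted p = 0.595), 2 of 9 leukocyte markers (adjusted p = 0.336), 2 of 6 endothelial markers (adjusted p = 0.336, all by Fisher's exact test) and 0 of 5 keratinocyte markers. Those 5 genes were all lower, with the secreted lysozyme gene LYZ at −1.08 (SE 0.05) in the authors' deposited table. Of the others, PDGFRB was at −1.98, CLDN5 at −3.15 and PECAM1 at −0.68, outside the rule for named genes and named after their values were seen, in the authors' deposited table. The 17 list calls treat genes as independent, and no correlation between genes could be estimated from the table, so their p-values are likely too small. Under the alternatives calls were lost 30 times. In 20 of these the list could not have passed even with all members left in its direction, mostly because few were left. The fatty acid list kept its 6 genes, all lower, in some of these and still lost its call. The other 10 losses fell on 6 lists, the heat shock, splicing, cholesterol, hypoxia, NRF2 and immediate early genes.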

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

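All alternatives given here were chosen after seeing the data. No paired analysis was possible because the table used here carries no value per library. For the same reason none of the alternatives planned beforehand was run: other tests and normalizations, other filters on low counts, the replicate block, the library sizes alone, leaving out each replicate in turn, another inter-gene correlation or set test, and other pseudocounts. How far 1 library decides any value is therefore unknown. The number of changed genes moved from 8727 to 4351 with a Bonferroni threshold, 5243 at 1.5-fold or more and 2741 at 2-fold or more, since each setting keeps a part of the same table. The small excess of higher genes (51.5%, exact binomial p = 0.00575) was not stable. It was no longer past the threshold at an adjusted p under 0.01 (50.8%), a mean normalized count of at least 183.4 (51.1%) or among protein-coding genes (50.5%). The excess turned over at an adjusted p under 0.001 (49.7%), with Bonferroni (49.2%), at 1.5-fold (46.4%) and at 2-fold (45.7%), and was gone once fold changes were centred on the median of the table (49.99%), by construction of that setting, which shifts every gene by 0.21. Setting the summed mean counts equal shifts every gene by 0.0971, less than the smallest change in the table, so it could turn no sign and tests nothing. For the other settings the cause was not tested. The lean of the autophagy machinery toward higher genes kept its direction throughout and missed the threshold only at 2-fold or more (80% higher, adjusted p = 0.326), where 5 members are left, too few to pass in any case. The lysosome list passed under none of the other settings that left it a gene. Of the other 16 called lists no direction turned. Heat shock chaperones, proteasome subunits, ribosomal proteins and the lysosome list have no value at 2-fold or more, since no member reached it. Calls were lost 30 times. In 20 of these the list could not have passed even with every member left in its direction, as in each loss of the autophagy, fatty acid, TGF-beta and YAP, metallothionein, proteasome, G2/M, ribosomal and hepatocyte lists. Where members had dropped out, such losses say nothing about stability. The fatty acid list kept its 6 genes, all lower, at an adjusted p under 0.001 (adjusted p of the list 0.0565, Fisher's exact test), with Bonferroni (0.0648) and when centred (0.0551). Its call there did depend on the setting. The 10 losses that could have gone otherwise were 4 of the heat shock list, 2 of splicing factors, and 1 each of the cholesterol, hypoxia, NRF2 and immediate early lists. The p53 targets gained a call at an adjusted p under 0.001 (83.3% higher, adjusted p = 0.0463). Of the 73 genes that the rule for named genes takes from the table, 71 passed Bonferroni and 50 reached 2-fold.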

Other observations

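Apart from the ribosomal protein list, the gene groups, families and count ranges in this part were chosen after seeing the data, and of the tests of explanations the one on the lowest mean count was chosen after its result was seen, as was the use of distinct matched genes in the test of genes without introns. Mitochondrially encoded mRNA and rRNA genes were higher, with 11 of 11 in the table above 0 (median log2 fold change 0.48, adjusted p = 0.00254 over 10 groups, Fisher's exact test) and 9 of them above the median of the table. Against random lists of like expression, with a mean of 65.4% higher, the adjusted p was 0.0470. Both tests take the genes as independent, so these p-values are likely too small. MT-RNR2, the large mitochondrial rRNA, was at 0.85 (SE 0.04) and MT-CO1 at 0.56 (SE 0.04) in the authors' deposited table. Mitochondrial tRNA genes did not pass, with 3 higher and 1 lower (adjusted p = 0.782, Fisher's exact test), the lower being MT-TD at −0.88 (SE 0.33) in the authors' deposited table. Of nuclear families, 26 of 30 MRPL genes (adjusted p = 0.00122 over 87 families, Fisher's exact test) and 14 of 16 COX genes (adjusted p = 0.0368) were higher, while MRPS genes, of the other mitochondrial ribosome subunit, did not pass with 8 of 11 higher (adjusted p = 0.462). Genes with EIF symbols, which cover translation initiation factors and some of their kinases and repressors, were higher in 39 of 44 cases (adjusted p = 1.5e-05), among them EIF2AK3, which encodes the ER stress kinase PERK, at 1.80 (SE 0.10) in the authors' deposited table. The other eIF2α kinase genes in the table went the other way, with EIF2AK4 at −0.84 (SE 0.08) and EIF2AK1 at −0.73 (SE 0.07) in the authors' deposited table. SEC genes, most of them parts of the ER translocon and of COPII vesicles, were higher in 18 of 22 cases (adjusted p = 0.0368), with SEC24D at 1.33 (SE 0.09) and SEC22B at 1.29 (SE 0.09) in the authors' deposited table.

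Some families leaned lower. Solute carriers were lower in 110 of 173 cases (adjusted p = 0.00122, Fisher's exact test), with the dicarboxylate carrier SLC13A3 at −3.50 (SE 0.16) and the glucose transporter SLC2A3 at −3.26 (SE 0.06) in the authors' deposited table. SLC33A1, an acetyl-CoA transporter of the ER membrane, was the highest of those with a mean normalized count of at least 183.4, at 1.84 (SE 0.14) in the authors' deposited table. Myosins (11 of 12, adjusted p = 0.0290) and semaphorins (12 of 14, adjusted p = 0.0406) were lower by the same Fisher's exact test. In the authors' deposited table MYO1A was at −1.45 (SE 0.25) and SEMA4G at −1.51 (SE 0.08). In all, 18 of 87 families passed. Transcripts annotated as antisense were lower in 81 of 125 cases (adjusted p = 0.00141). The share higher, 35.2%, lay below the mean of 48.3% in random lists of like expression (adjusted p = 0.00933), but without strand their reads cannot be separated from those of overlapping genes, and lincRNAs split 56 to 56 (adjusted p = 0.862).

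Noncoding host genes of small nucleolar RNAs, which are spliced and are known substrates of nonsense-mediated decay, were all higher, 12 of 12 in the table (median 0.98, adjusted p = 0.00171, Fisher's exact test). SNHG17 was at 1.68 (SE 0.10), SNHG1 at 1.45 (SE 0.07) and GAS5 at 1.11 (SE 0.09) in the authors' deposited table. Of the hosts, 91.67% stayed above the median of the table (p = 0.00340 after centring, Fisher's exact test). They thus leaned higher than the other changed genes. The table holds only genes past the threshold, so its median does not measure a shift of the scaling common to all genes. The test therefore cannot decide on such a shift. Slower nonsense-mediated decay, the biological candidate explanation, cannot be told apart from other causes: of 7 listed decay factors that are themselves decay substrates, 3 are in the table and 66.67% of those were higher, too few for the 5 the test required. In the same direction, all 9 snoRNA genes in the table were higher (median 1.26, adjusted p = 0.00803, but 0.0640 against random lists of like expression), at a median mean normalized count of 18.3, where reads of the host may be counted for the snoRNA.

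All 37 ribosomal protein genes in the table were higher, by a median of 0.42. Of them, 100% stayed above the median of the table (p = 6.71e-12 after centring, Fisher's exact test). They thus leaned higher than the other changed genes, past the 90% set beforehand against a common shift of the scaling. For the same reason as with the host genes, that test cannot decide on such a shift. A bias toward short, abundant transcripts remains possible: 77.3% of other protein-coding genes matched on transcript length and mean normalized count, 20 for each, were higher, with a median of 0.39 close to that of the ribosomal genes. A gene was counted each time it was matched, and the share of distinct genes was not computed. That share fell between the 75% and the 90% set beforehand to decide, so a coordinated change and such a bias cannot be told apart without reads or a value per library.

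Genes with very low counts were mostly higher. Under a mean normalized count of 10, 282 of 344 genes (82.0%) were higher, against 41.6% of the 4199 genes from 30 to 1000 and 57.9% of the 3645 genes at 1000 or more. The first split differed from the rest of the table (p = 3.38e-33, Fisher's exact test). Processed pseudogenes, with a median mean normalized count of 14.2, were higher in 57 of 66 cases (adjusted p = 2.88e-08, Fisher's exact test). Their share of 86.4% lay above the mean of 66.7% in random lists of like expression (adjusted p = 0.0060), so they leaned higher than their level alone would bring. Deeper libraries on the higher side could let more such genes pass. The lowest mean count of higher genes was 1.058 times that of lower genes, with a bootstrap 95% interval of 0.959 to 1.06. Each lowest count is set by the lowest gene alone, and resampling cannot go below it. Neither the ratio nor its interval can therefore decide on depth. A low background of reads that grows with transcript length may also contribute; the transcripts of higher genes were 1.258 times as long as those of lower genes (permutation test, p = 0.230), a void comparison because only 63.1% of these genes had a length. No biological explanation was tested for this pattern.

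A further hypothesis was that a general slowing of splicing would spare genes without introns. Of 108 single-exon protein-coding genes, 60.2% were higher (exact 95% interval 50.3% to 69.5%), which was 10.46 percentage points more than the 49.7% of multi-exon genes matched on length and mean normalized count. Counting each matched gene once, 48.0% of 1753 were higher, and the difference passed (Fisher's exact test, p = 0.0170). It did not pass against all 7416 multi-exon genes without matching (50.3% higher, p = 0.0521, Fisher's exact test). The matched difference lay narrowly over the 10 points set beforehand, in the direction of the hypothesis only if higher means isoginkgetin over DMSO. The single-exon genes include the mitochondrially encoded mRNA genes, which were all higher and are not made in the nucleus. These cannot bear on a slowing of splicing. Leaving them out can only lower the 60.2%, so the narrow margin over the 10 points may rest on them. The difference without them was not computed. The values therefore cannot decide on the hypothesis. Other ways in which single-exon genes differ were not tested. Intron retention itself cannot be read from gene-level values.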
